A study of Mus musculus with 16 samples.

How the data were processed

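Genomic DNA from the tails of 8 mice was measured on 16 arrays of 973116 spots, of which 966371 were not controls. After 36 probes on unplaced contigs were left out, 950713 distinct probes remained, with 950622 on autosomes, 68 on X and 23 on Y. Neighbouring autosomal probes lay 2053 bp apart at the median, and the probes were 60 bases long. Each animal was measured against the same reference male with the dyes both ways.

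The deposited scanner files hold spot intensity values from Agilent Feature Extraction 10.7.1.1, per the file headers. Per the file headers, the processed intensities were background-subtracted and dye-normalized within each array by a linear method, on build mm9. The deposited log10 ratios are red over green, per the file headers. The deposited series table holds log2 ratios; how they were made is not given in the sources used here. Set against the scanner values, they ran reference over animal on every array with correlations of 0.989 to 1.00 and medians between -0.0066 and 0.015. They were identical to them on 1 array, so some further correction that is not stated was applied to the rest. They were used as an alternative.

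Log2 ratios were computed from the processed intensities, turned to animal over reference, averaged over spots of a probe and centred on the autosomal median of each array, with no loess or quantile step. Between 117 and 198 spots per array that the scanner software marked as outliers were left out, and saturated spots (3, on 1 array) were kept. The 2 arrays of an animal were averaged. The sample groups and replicate numbers came from the labels. Arrays of the parents were dimmer, with median background-subtracted green signals of 64.0 to 83.3 against 111 to 175 in the progeny, and between 98.8% and 99.96% of probes were well above background in the animal's channel. The robust probe SD of an animal's mean ratio was 0.16 in both parents and 0.10 to 0.13 in the progeny. After the sign was turned, the orientations of an animal correlated between -0.45 and -0.13 across probes, which are not independent replicates. The SD over probes was larger for the half-difference of the orientations, 0.15 to 0.21, than for their mean, 0.11 to 0.18. The number of arrays limits the precision. Both parents were scanned on day 1 and the progeny in pairs on days 2, 3 and 4.

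Intervals of consecutive probes were called on the mean of both orientations at a score of at least 6, at least 3 probes, a mean of at least 0.25 in size and at least 0.25 in the same direction in each orientation. The score is the summed ratio divided by the robust probe SD and the square root of the number of probes. Calls sharing a probe and a sign were merged, and an animal carried a region at a score of at least 3 and a mean of at least 0.25. Regions of progeny only were tested against 10000 autosomal windows drawn at random, with no values permuted, as for every empirical permutation p below. These choices, and those listed with the alternatives as planned, were made before the data were examined. The random probe orders (20), the joining of the chromosome 14 intervals, windows of 5 and 20 probes, intervals of at least 10 probes, the requirement on every probe, and the series table, single orientation and bright-probe means of the long regions were added later, as was wave removal for progeny minus parents.

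The planned tests per gene and the fixed gene lists (antigen receptor loci, colony copy number genes, multicopy families, repair genes, Y genes, their X partners and pseudoautosomal genes) were not run, because the files used here carry no gene names and the gene table at hand is on another build than mm9. Windows of 10 consecutive autosomal probes took the place of genes, and limma 3.58.1 in R 4.3.3 tested them with lmFit and eBayes. With parents and progeny on separate scan days, scan day was fitted as a random block with statmod 1.5.0. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The text names the 10 progeny-only regions of highest score, the 10 of highest score among the other regions, and up to 10 windows per direction past each test with 1 direction in every animal. The part of that rule on regions carried by all 8 animals selected none. The window of progeny minus parents and the loss of 10 probes in progeny 5 were named after their values were seen.

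The scripts were tested on simulated data. Segments were added to shuffled probes of progeny 1 and of the male parent. All 22 segments of 40 probes at 0.3 were found in each. At 10 probes and 0.3, 77.3% were found in progeny 1 and 45.5% in the male parent, and at 3 probes and 0.3, 18.2% and 0%. Before any segment was added, the shuffled probes of progeny 1 gave 194 calls and those of the male parent 76. In 95054 simulated windows the family test found all 100 changes of 0.3 with 0 false calls, and progeny minus parents found 86% of changes of 0.3 and all of 0.5 with 6 false calls over both sizes. Each animal's windows were shuffled separately, which removes shifts shared between animals, so these false calls need not carry over to the real tests.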

Results

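The genomes of 1 mouse family were screened for differences in DNA copy number by array comparative genomic hybridisation, in which the DNA of an animal and of a reference are labelled with different dyes and compete for the same probes. Tail DNA of a male parent, a female parent and 6 progeny of the strain labelled C57 Black/J6Nrs was compared with DNA of 1 reference male of the same colony. Each animal was hybridised on 2 arrays with the dyes exchanged, so that 16 arrays describe 8 animals, and the 2 arrays of an animal were counted as 1 replicate. The series title speaks of males exposed to gamma rays at 1 mGy per day for 400 days, while its design text calls this family's male non-irradiated. No comparison with another exposure was made, and no difference below is a treatment effect. Values are log2 ratios of the animal over the reference, so a gain in the animal is positive. The deposited series table runs in the opposite direction, reference over animal. Positions are on mouse build mm9, and probes are named by position only, because the files used here carry no gene names.

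The first comparison asked whether the sex chromosomes gave the dose the labels state, since the sexes of both parents and of the reference are known. The female parent had a median X ratio of 0.91 over 68 probes, and her 2 arrays gave 0.86 and 0.89. Her median Y ratio over 23 probes was -2.04, with -2.20 and -1.84 on the 2 arrays. Both medians were smaller in size after another background correction, which adds an offset to both channels, as given with the alternatives below. The male parent lay at 0.03 on X and 0.03 on Y. Progeny 6 had an X ratio of 0.94 and a Y ratio of -2.59. Progeny 1 to 5 had X ratios between 0.00 and 0.03. Their Y ratios lay between -0.17 and 0.02. The labels give no sex for the progeny, and these values define no group. The X and Y medians of the female parent and of progeny 6 lay beyond all of 10000 random autosomal windows of as many probes (empirical permutation p = 0.0001 each, the smallest possible, Benjamini-Hochberg adjusted p = 0.0004 over 16 values). The Y ratio of progeny 3, -0.17, also passed (adjusted p = 0.00064 from the same permutation), but its 2 arrays gave -0.30 and 0.01. Only 9 of the 23 Y probes of the female parent and 13 of those of progeny 6 were well above background on both arrays, with medians of -1.29 and -1.48, so the Y medians over all probes include probes that have only a bound.

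**Figure D1:**
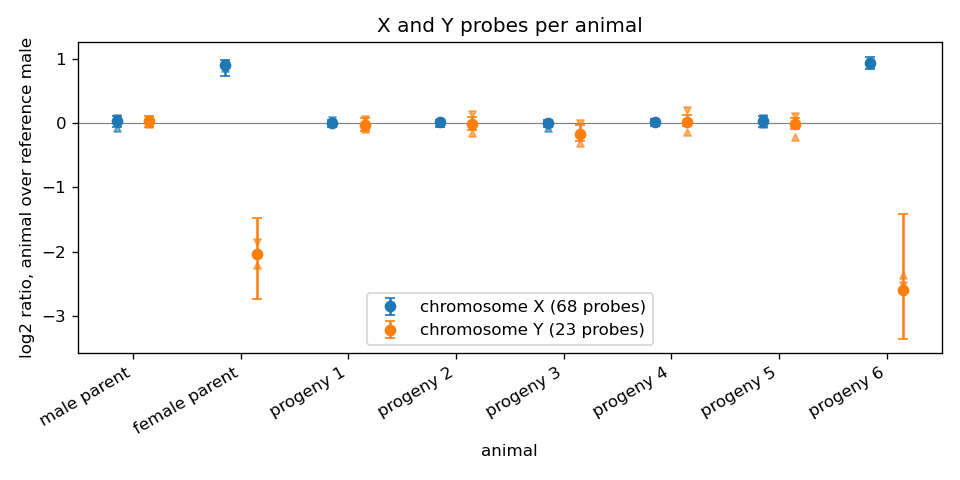
Median log2 ratio of the animal over the reference male for X and Y probes of each of the 8 animals, with bars for the quartiles over probes and triangles for the single arrays (upward, animal in Cy5; downward, animal in Cy3). The female parent and progeny 6 lie at 0.91 and 0.94 on X and at -2.04 and -2.59 on Y, and the other animals lie near 0.

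The clearest copy number difference within the family was a gain on chromosome 4 from 101110482 to 101270535, covering 74 probes and 160054 bp. It was carried by the male parent at 0.56 ± 0.02 (standard error over probes) and by 4 of the 6 progeny. Progeny 2 had 0.56 ± 0.01, progeny 3 had 0.56 ± 0.01, progeny 5 had 0.53 ± 0.01 and progeny 6 had 0.54 ± 0.02. The 5 carriers had a mean of 0.55 ± 0.01 (SD, n = 5). Each carrier's mean lay beyond all of 10000 random windows of as many probes (empirical permutation p = 0.0001, the smallest possible, adjusted p = 0.00032 over 32 values). Here and in the long regions below, the region had been called on these same values, a choice the p does not account for. The female parent, progeny 1 and progeny 4 lay at -0.03, -0.01 and 0.00. The share of carriers among the progeny was 66.7%, with an exact Clopper-Pearson interval of 22.3% to 95.7%. The called start differed between carriers only between positions 101110482 and 101111896, and the called end only between 101268843 and 101270535. In each carrier both dye orientations gave a mean above 0.52. One extra copy on a base of 2 corresponds to a log2 ratio of 0.58, or 0.53 when scaled by the X response of the female parent. That response was smaller after a background correction that adds an offset to both channels, as given with the alternatives below.

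**Figure D2:**
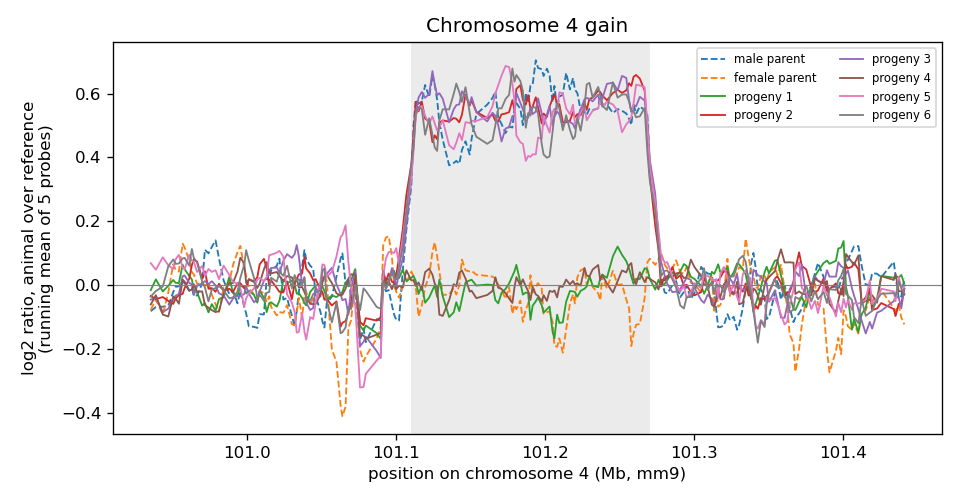
Running mean over 5 probes of the log2 ratio (animal over reference) along chromosome 4 in Mb on mm9 for each of the 8 animals, parents dashed, with the region shaded. The male parent and progeny 2, 3, 5 and 6 rise together to about 0.55 and return to 0 at the same edges, while the other animals stay near 0.

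The comparison of parents with progeny asked which differences appear in progeny and in neither parent. A gain on chromosome 14 was found in progeny 1 alone, in neighbouring intervals from 26704333 to 26775821 with 37 probes and from 26789368 to 26812379 with 12 probes. Joined after the values were seen, they covered 52 probes and 108047 bp, and progeny 1 had a mean of 0.29 ± 0.01 (standard error over probes; empirical permutation p = 0.0002, adjusted p = 0.000457). The other 7 animals lay between -0.02 and 0.00. Over the joined stretch, the dye orientations of progeny 1 gave 0.34 with the animal in Cy5 and 0.24 with the animal in Cy3. The lower of these lies under the 0.25 that calling an interval requires in each orientation. The carrier rule takes the mean of both orientations. The running mean of progeny 1 was still 0.29 at position 26832999, and the next probe lay at 26944906, so the right edge is not resolved. On the left it was already 0.32 at 26701673, before the called start. The joined length may therefore be too short on both sides. The level was 0.24 lower than the lowest carrier of the chromosome 4 gain, with a standard error of 0.02 over probes, which differ between the regions.

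**Figure D3:**
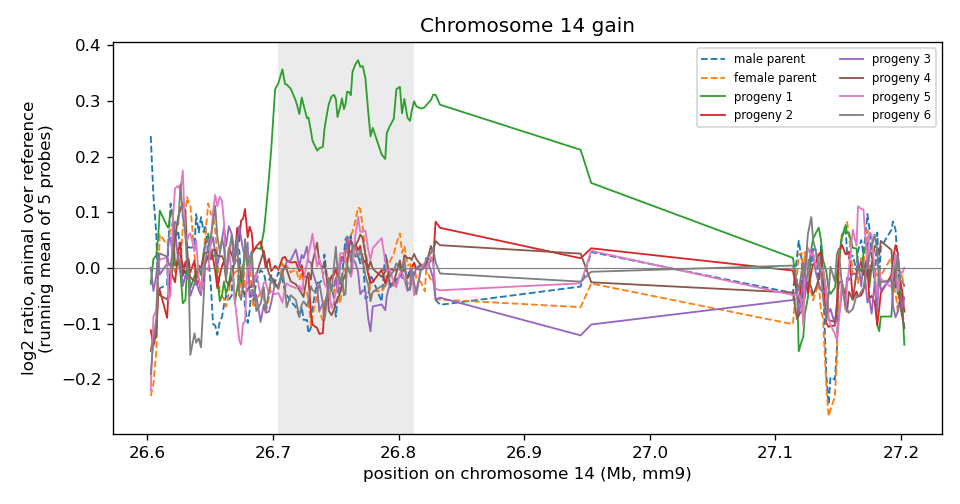
Running mean over 5 probes of the log2 ratio (animal over reference) along chromosome 14 in Mb on mm9 for each of the 8 animals, parents dashed, with the joined region shaded; lines cross stretches without probes. Progeny 1 lies near 0.29 across the region and the other animals near 0.

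A gain on chromosome 8 from 102129465 to 102254870, with 45 probes, was called in progeny 6 at 0.27 ± 0.02. The female parent had a mean of 0.20 ± 0.04 over the same probes, which is under the carrier minimum of 0.25, so the fixed rule counts the region as present in progeny only. The fixed caller did call a gain of 8 probes in her inside it, from 102166134 to 102191887 at 0.36, so the region is not absent from the parents. Her mean was nevertheless beyond nearly all random windows (empirical permutation p = 0.0002, adjusted p = 0.000457 over 32 values). The other 6 animals lay between -0.05 and 0.00. The call of either animal depends on the setting: progeny 6 had 0.24 with a running median over 500 probes removed, and the female parent had 0.26 with the animal in Cy3 only.

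A loss on chromosome 14 was called in all 8 animals within the stretch from 53390264 to 54405220, which holds 117 probes. Over the whole stretch the animals had means between -0.28 and -0.17, with -0.23 ± 0.04 (SD, n = 8), and the female parent and progeny 5 passed the carrier rule over the full length. Each animal's mean lay beyond nearly all random windows (empirical permutation p between 0.0001, the smallest possible, and 0.0004, adjusted p at most 0.0008). From 53533308 to 53629733 the animals lay close together at -0.30 ± 0.02 (SD, n = 8). From 54078616 to 54298759 they spread from -0.39 to -0.05. All 8 animals share the reference male, so this shared difference cannot be assigned to the family or to the reference.

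**Figure D4:**
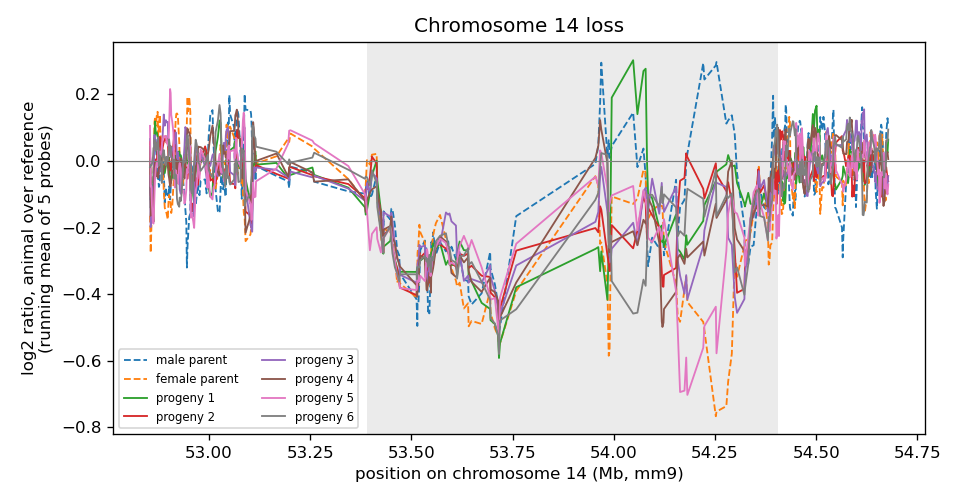
Running mean over 5 probes of the log2 ratio (animal over reference) along chromosome 14 in Mb on mm9 for each of the 8 animals, parents dashed, with the region shaded. All animals fall together in the left part of the region, and they separate in the right part, where single animals lie on either side of 0.

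The test across the whole family used means over windows of 10 consecutive autosomal probes in place of genes. Of 95054 windows, 7 were higher and 5 were lower than the reference in limma's moderated test (Benjamini-Hochberg adjusted p under 0.05 and a mean of at least 0.25 in size). The 7 higher windows all lay in the chromosome 4 gain, which 5 of the 8 animals carried, and 1 of them, from 101224038 to 101245761, was above 0 in every animal, with a mean of 0.36 ± 0.28 (SD, n = 8; limma adjusted p = 0.00107). The 5 lower windows lay on chromosome 14 between 53430657 and 53716408 and were below 0 in every animal. Their means ran from -0.26 to -0.39, and the lowest, from 53629682 to 53716408, had -0.39 ± 0.05 (SD, n = 8; limma adjusted p = 2.21e-14). The others began at 53430657 (-0.26), 53512675 (-0.33), 53537334 (-0.34) and 53553702 (-0.27). The test leaves out the reference animal's own spread and treats parents and their progeny as independent animals. In the chromosome 4 window the female parent, progeny 1 and progeny 4 lay at only 0.01, 0.01 and 0.03. Its limma standard error was 0.06, because limma borrows from windows with little spread between animals. Its p is therefore no measure of a gain shared by the whole family.

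Progeny minus parents gave 1 higher window and no lower one in the same limma test of 6 progeny against 2 parents, while 12132 windows had an unadjusted p under 0.05. The window, on chromosome 1 from 100371223 to 100390135, had a difference of 0.31 ± 0.05 (standard error; limma adjusted p = 0.0354). The progeny had a mean of 0.06 and the parents of -0.25; it is named although the fixed rule does not select it, because it is the only one. The call was lost when any of progeny 1 to 5 was left out and in each dye orientation alone. It was also lost in windows of 20 probes and after normexp background correction, whose added offset shrinks ratios. Higher and lower windows numbered 7 and 3 without the male parent, 3 and 35 without the female parent, and 7 and 10 in windows of 5 probes. Both parents were scanned on day 1 and all progeny on days 2 to 4, and the parents' arrays were dimmer, so progeny minus parents and scan day cannot be told apart.

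The fixed caller gave 1125 intervals over the 8 animals, 139 gains and 986 losses, and most of these could not be told from chance runs of single probes. Intervals of 3 to 4 probes made up 126 gains and 926 losses. When the autosomal probes were put in random order, which leaves no segment in place, 20 such orders gave 127.7 ± 9.6 gains and 916.0 ± 21.9 losses of that length (mean ± SD over orders). Intervals of 5 to 9 probes numbered 5 gains and 51 losses, against 5.75 ± 2.88 and 52.2 ± 5.77 in random order. Intervals of 10 or more probes numbered 8 gains and 9 losses, against 0 to 2 gains and 0 to 3 losses in any of the 20 orders. The longest interval of an order had 8 to 15 probes. By animal, the number of intervals lay within the range of the 20 orders in all but progeny 6. That animal had 65 intervals, 3 of them of 10 or more probes, against 42 to 63 in random order. Of the 17 intervals of 10 or more probes, 5 were the chromosome 4 gain, 8 the chromosome 14 loss, 2 the chromosome 14 gain of progeny 1 (37 and 12 probes, the second no longer than random order gave) and 1 the chromosome 8 gain. The remaining 1, a loss of 10 probes on chromosome 4 from 85898549 to 85924620 in progeny 5 at -0.29, was no longer than random order gave. The random order was added after the calls were seen; the control fixed beforehand, calling on the half-difference of the dye orientations, gave 252 intervals and did not show this.

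**Figure D5:**
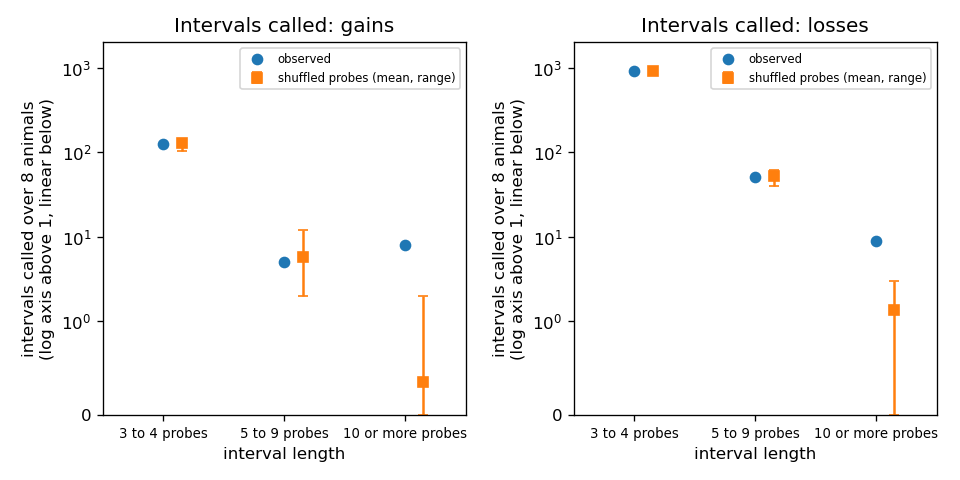
Intervals called over the 8 animals by length in probes, gains left and losses right, as observed (circles) and with autosomal probes in 20 random orders (squares, mean; bars, lowest to highest), on an axis that is logarithmic above 1 and linear below. Counts at 3 to 9 probes overlap those of random order, and those at 10 or more probes, 8 gains and 9 losses, lie above it.

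Merging the calls gave 827 regions, of which 259 were carried by a parent and a progeny, 157 by a parent only and 403 by progeny only; 8 had no carrier over their full length and none was carried by all 8 animals. Random order gave 387 to 447 regions of the progeny-only kind, so their number is no measure of differences that arose in the progeny. Of the 403, 374 passed the window test of carrier minus parents after adjustment, but each had been chosen as an extreme and the test does not account for that choice. Among the 10 of highest score, 8 were losses of 3 to 7 probes with scores between 10.1 and 13.1, and random order reached scores of 10.8 to 16.2 for its best such region. The best of the 8, on chromosome 9 from 112402282 to 112409275, had -0.76 in progeny 2 over 3 probes that ranged from -2.11 to 0.00. Progeny 3 had the lowest value on chromosome 6 from 59718760 (-0.65), chromosome 18 from 11555614 (-0.34), chromosome 8 from 131388351 (-0.76) and chromosome 15 from 76181364 (-0.72). Progeny 2 had the lowest on chromosome 10 from 27005348 (-0.62), chromosome 4 from 139220172 (-0.42) and chromosome 1 from 109580817 (-0.59). The parents were not always near 0. The male parent had -0.25 on chromosome 8 from 131388351, the female parent had -0.21 on chromosome 18 and -0.17 on chromosome 6, and the parents had -0.17 and -0.22 on chromosome 10. On chromosome 4 from 139220172 they had -0.18 and -0.20. When every probe had to reach 0.25, the last region shrank to 3 probes from 139223770 that all 8 animals carried, the parents at -0.30 and -0.34, and it was no longer confined to progeny.

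A short loss that exceeded random order lay on chromosome 3 from 25417435 to 25432738. Its 3 probes had a mean of -1.58 ± 0.26 in the female parent and -1.62 ± 0.35 in progeny 6 (standard error over probes), and the other animals lay between -0.06 and 0.02. Its score of 22.5 compares with at most 16.5 for a loss in random order. Another 4 losses among the highest scores of the regions not confined to progeny were carried by the female parent and progeny 6. They lay on chromosome 6 from 104236953 (-0.57 and -0.70), chromosome 5 from 123592752 (-0.55 and -0.58), chromosome 9 from 35853071 (-0.36 and -0.50) and chromosome 11 from 112955152 (-0.49 and -0.58), with scores of 11.0 to 13.1, which random order also reached. In both animals the lowest single probe of these 4 lay between -2.69 and -1.96, while the median probe lay between -0.33 and 0.10. A loss on chromosome 3 from 19052867 was carried by both parents (-0.38 and -0.37), progeny 2 (-0.29) and progeny 4 (-0.58). A gain on chromosome 13 from 95703166 had means from 0.16 in the female parent to 0.47 in progeny 3 over 5 probes, but the highest probe lay between 1.14 and 2.24 and the median probe between -0.06 and 0.11. A gain on chromosome 11 from 76354520 was carried by the male parent (0.31), progeny 2 (0.34) and progeny 6 (0.25), while progeny 1 and progeny 4 had -0.26 and -0.30. These last 3 had scores of 11.2 to 12.4, also within those of random order.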

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

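Of 28 sets of values of the 6 progeny, 11 had 1 animal far from the other 5, with its gap to the nearest above the 95% critical value of Dixon's ratio; chance alone gives this in about 1 of 20 groups, and most regions had been chosen as extremes. Tests chosen after their result was seen were the comparison of short losses with those of the half-difference, those of the level of the chromosome 14 gain and of the scan day of progeny 2, and the test of the spread between animals at the chromosome 14 loss was run only after a first run of its trend. Progeny 6 stood apart on X (0.94) and Y (-2.59). It also stood apart at the chromosome 8 gain (0.27) and at losses on chromosome 3 from 25417435 (-1.62), chromosome 6 from 104236953 (-0.70), chromosome 5 from 123592752 (-0.58) and chromosome 11 from 112955152 (-0.58). Progeny 2 stood apart on chromosome 9 from 112402282 (-0.76) and chromosome 1 from 109580817 (-0.59), progeny 3 on chromosome 15 from 76181364 (-0.72) and progeny 1 at the chromosome 14 gain (0.29). The labels give no group among the progeny, so no explanation by group was tested for the patterns that follow. The measured X and Y values do set progeny 6 apart, near those of the female parent (0.91 and -2.04), but they were not used as a group.

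For the gain of progeny 1 on chromosome 14, a scan-day effect is argued against by progeny 2, scanned on the same day, at -0.0093 ± 0.0096 (standard error over probes). For a full extra copy on a base of 2 in every cell, the level lay 0.24 below the lowest carrier of the chromosome 4 gain. This exceeded 2 standard errors over probes but sets different probes against each other. It argues against that explanation only if they respond alike, which was not tested. A base of more than 2 copies stays open. For the level, 5 copies over 4 correspond to a log2 ratio of 0.32, against 0.29 in progeny 1, which was not tested. The region's probes had a median reference-channel log2 signal 1.84 above the autosomal median. This passed the test's upper bound of 0.29 from random autosomal windows, as a base of more than 2 copies would predict. The test was set aside as unable to decide only after it had been run. It sets different probes against each other, whose brightness depends on sequence. The random windows also hold such differences, but a single region of unusual sequence could still exceed them, so no conclusion is drawn. An event in part of the cells was not tested.

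For the chromosome 14 loss in all 8 animals, a flat extra copy in the reference male stays open. The region means differed by more than random windows of the same animals (empirical permutation p = 0.0007), which sets single animals against array noise only, but not by more than their standard errors over probes allow (chi-square 10.6 on 7 degrees of freedom, 95% point 14.1). Those standard errors also include the change along the stretch. A graded loss, as rearranged antigen receptor loci of lymphocytes in the tissue would give, could not be settled. The ratio changed by 0.18 from the first probe to the last (95% bootstrap interval 0.08 to 0.27, permutation p = 0.0016), short of the 0.2 set beforehand. The loss was weaker on the right, at -0.12 from 54304425 against -0.24 from 53390264 to 53522023. The stretch joins calls that ended at different places, from 53954595 in the male parent to 54405220 in progeny 5. Joining them can by itself give such a change, so the trend cannot show a graded loss. Whether the segment overlaps such a locus was not analysed here.

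For the excess of short losses over short gains, dye or array noise that differs between orientations stays open. The half-difference gave fewer short losses, 174 against 926, but it too had more losses than gains, 174 against 37. Single extreme probes may account for most: 6.37% of short losses had every probe at -0.25 or lower, and random probe order gave 916.0 ± 21.9 short losses. Whether the reference animal carries part of the difference stays open, since the other 7 animals had a median of -0.18 over these probes, between the bounds set beforehand.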

How the results depend on the processing

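Alternatives chosen after the values were seen were 10 or more probes, every probe at 0.25, windows of 5 and 20 probes, and the series table, single dye orientations and bright probes for the means of the long regions. The chromosome 4 gain of the male parent stayed above the carrier minimum under each of the 6 alternatives run for it, between 0.42 and 0.57. The chromosome 14 gain of progeny 1 fell under it with the animal in Cy3 only, at 0.24. Requiring every probe at 0.25 left no region at that gain or at the chromosome 8 gain. Their lowest probes were 0.16 in progeny 1, over its interval of 37 probes, and 0.01 in progeny 6. The chromosome 4 gain stayed, with 5 carriers. Of the alternative means of the long regions in other animals, 169 stayed on their side of the minimum, 6 fell short of it and 5 newly passed it, all of these 11 in the chromosome 14 loss or the chromosome 8 gain. The normexp correction took median spot signals here, because the files used hold no mean signals. It also added an offset of 50 to both channels, which shrinks ratios, most in dim probes. Changes after normexp are therefore not separated from that offset. After normexp the female parent had 0.55 on X and -0.32 on Y, and the median correlation of the orientations was -0.42. With the animal in Cy5 only she had 0.86 on X and the male parent -0.012 on Y, which was also -0.012 in the series table.

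Counts of calls of all lengths, 139 gains and 986 losses, changed with each of these settings. Gains and losses numbered 29 and 152 at a score of at least 8, 38 and 303 at 5 or more probes, 72 and 357 at a mean of at least 0.4, and 19 and 269 after normexp. Against the median of the other 7 animals they numbered 298 and 300. With the animal in Cy3 only they numbered 298 and 295, losses with Cy5 only numbered 539, and gains on probes well above background numbered 25. Calling at 10 or more probes gave 12 and 23, and requiring every probe at 0.25 gave 14 and 61, against 11.4 and 52.9 in random order. Regions numbered 137 at a score of at least 8 (1 in all 8 animals, 61 parent and progeny, 16 parent only, 59 progeny only). At 5 or more probes they numbered 267 (34, 60 and 162 of the last 3 kinds), and after normexp 160 (47, 3 and 106). With every probe required they numbered 72 (1 in all 8 animals, then 21, 22 and 28). A carrier score of 4.5 left 97 of parent and progeny. The 12 and 23 called at 10 or more probes exceed the 8 and 9 of that length called at 3 or more. Intervals are kept without overlap, highest score first, so at 3 or more probes a short call can block a longer one around it. No random order was run at 10 or more probes, so the added calls are not shown to be segments. The causes of the other changes were not tested.

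The family test gave 87 higher and 1440 lower windows with no minimum size, 15 and 13 in windows of 5 probes, and 3 and 3 in windows of 20, where fewer windows are tested. Lower windows numbered 3 after wave removal and 8 in each dye orientation alone. Leaving out 1 animal gave 7 higher and 5 to 7 lower. Progeny minus parents gave 3 and 4 with no minimum size and 7 and 10 in windows of 5 probes. It gave 0 higher in windows of 20 probes, after normexp and in each orientation alone. Leaving out 1 animal gave 0 to 7 higher and 0 to 35 lower, the highest being 7 without the male parent and 35 without the female parent, where the lone parent is assumed to vary like the other animals. Scan day as a random block left the tests at 7 and 5 and at 1 and 0, but for progeny minus parents it separates nothing, since no day holds both: its correlation was -0.188, and windows with an unadjusted p under 0.05 rose from 12132 to 16902. Causes were not tested. No paired analysis was possible because parents and progeny share no replicate numbers that pair them. At least 5 probes per gene, and normexp and leaving out animals for the fixed gene lists, were not run, since no genes were assigned. Low signal over background limits the Y probes of the female parent and progeny 6. In every other animal, the male parent with his dim arrays included, all 23 Y probes were well above background. Low signal also limits the precision of the parents' arrays.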

Other observations

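Both tests here were chosen after shared losses of the female parent and progeny 6 had been seen. Of 45 loss regions carried by the female parent and exactly 1 progeny, 18 were shared with progeny 6, on 12 chromosomes, and between 2 and 8 with each of the others. One hypothesis was that the female parent passed on deletions independently to her progeny. An exact one-sided binomial test against 1 in 6 gave p = 0.00017, but it counts the sharing that prompted it, over regions that are not shown to be separate deletions, so the hypothesis is left open.

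A second hypothesis was that autosomal probes low in the female parent share sequence with the Y chromosome, which she lacks. On 137 autosomal probes at -1 or lower in both of her orientations, progeny 6 had a median of -0.092, above the bound of -0.25, and the other 6 animals lay between -0.42 and -0.35. Shared Y sequence therefore could not account for these probes as a set. In progeny 6, 13 of the 137 were at -1 or lower in both orientations, out of 25 such autosomal probes in that animal. The male parent had 6 of 53, progeny 1 had 15 of 34, progeny 2 had 10 of 26, progeny 3 had 23 of 86, progeny 4 had 7 of 25 and progeny 5 had 14 of 53. The 3 probes of the chromosome 3 loss from 25417435 lay at -1.25 or lower in the female parent and progeny 6, while the other 6 animals had means between -0.06 and 0.02. Whether shared Y sequence accounts for single probes such as these was not tested and stays open.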
